A study of Homo sapiens with 8 samples.

How the data were processed

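The samples were polyA+ RNA from HEK293T cells: 4 IP libraries made with an m6A antibody, 2 from control and 2 from PCIF1 knockdown cells, and their 4 inputs. Per the labels, libraries came from a directional kit, were sequenced as paired-end reads on an Illumina HiSeq instrument, and were aligned to hg19 with TopHat2 2.0.13. The submitters' notes also name Trim Galore, HOMER 4.8 and Cuffdiff 2.2.1; the step each was used for is not given in the sources used here.

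Each IP library had 1 peak list, which the authors made with MACS2 2.1.1.20160309 from that IP against its own input, per the file headers. The headers give a q cutoff of 0.01, no fragment model, an extension of 200 bp, paired-end mode off and at most 1 tag per position. Inputs had no list of their own and entered only through these calls. The pileup column holds the deposited signal, the extended IP tags piled up at the summit, which is not comparable between lists. The columns of -log10 p and -log10 q hold the MACS2 test of the IP against the local input, per the file headers. The fold is the ratio of IP to local input at the summit, as deposited by the authors, and was used here to rank peaks within a list and, in 1 alternative, as a minimum. Folds printed for several lists are each list's own value and were not tested between lists. Positions are hg19 coordinates in bp, per the file headers. The tag size in the headers was 128 bp in control 1, 125 bp in control 2, 109 bp in knockdown 1 and 92 bp in knockdown 2. The IP libraries held 32049497, 29598847, 28629071 and 35791571 tags in that order, with a redundant rate of 0.72, 0.71, 0.71 and 0.74. The inputs held 34475296, 34056933, 34565812 and 32805153 tags. Tags are PCR reads without molecular identifiers.

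The annotation was GENCODE v44 lifted to GRCh37, with 78703 starts of protein-coding transcripts in 19821 genes, and sequence came from GRCh37. Peaks on the mitochondrial chromosome were left out (8, 10, 10 and 5 peaks), because the hg19 and GRCh37 versions of that sequence differ. Each summit took the first class that applied: 5' end (100 nt upstream to 200 nt downstream of a protein-coding start), stop codon (within 200 nt), 3' UTR, 5' UTR, coding sequence, non-coding exon, intron or intergenic. Strand of the reads was not used. The peaks of the 4 lists were merged where they overlapped by 1 bp or more, and a library held a region if it had a peak in it. A region took the summit of its peak with the highest within-list percentile of -log10 p.

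Values per library were compared with an exact permutation test, two-sided. Tables over regions or genes were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over classes or lists. Regions are not replicates, so these tests describe the 4 lists. GC content was compared with a permutation test with 100000 permutations and a bootstrap with 1000 draws. The motif background came from windows 1000 nt to either side. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6, pysam 0.24.0 and Matplotlib 3.10.9 were used.

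The comparisons, their tests, the rule for named genes and 13 gene lists were chosen before the data were examined, except where a comparison is said to have been chosen later. The share of 5' end regions that were knockdown-only, the count of knockdown-only regions and the ratio of group-specific regions to the larger crossed count were also added after the data were seen. The lists were the m6A and cap methylation machinery, cytosolic and mitochondrial ribosomal proteins, oxidative phosphorylation subunits, splicing factors, translation factors, chaperones, cell cycle genes, chromatin regulators, zinc finger genes, interferon-stimulated genes, replication-dependent histones, and markers of blood, liver, muscle and neurons. Genes were ranked by the smaller percentile of the fold within the 2 lists of a group. The rule names the 10 top genes with a control-only 5' end region, and the 5 top genes each with a knockdown-only 5' end region, a 5' end region in all 4 lists, and a control-only, knockdown-only or shared region elsewhere. It also names PCIF1, the machinery genes with a region in both libraries of a group, and up to 4 genes of each other list with a 5' end region in both controls. Of the genes the rule names, 1 is not reported here.

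Alternatives were a -log10 q of at least 10, a fold of at least 4, lists of equal length (20937 peaks), peak by peak overlap of 50%, windows of 50 nt upstream to 100 nt downstream and 200 nt upstream to 500 nt downstream of the start, peaks that cover the start, the most upstream start of each gene, loss from at least 1 list, each replicate left out, and a block for replicate number. Comparison with other mRNA exon regions and matching on GC content or strength were added after the data were seen.

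The procedure was tested on simulated data, 20 sets of lists per setting with a median of 21466 regions tested. With no loss, the loss test and the direction test each gave p below 0.05 in 1 set. With 10% of 5' end regions removed from both knockdown lists they did so in 20 and 19 sets, and with 30% removed in 20 and 20. With 20% of zinc finger regions removed, that list was called in 20 sets. Each simulated library called every region independently, with the same chance in all libraries and classes. In the real lists the control-only share ran from 1.75% at stop codons to 23.1% in introns. The simulated rates of calls therefore do not carry over to the real lists.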

Results

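The data were peak lists from m6A-seq, in which fragmented RNA is immunoprecipitated with an antibody against N6-methyladenosine (m6A) and compared with the RNA before immunoprecipitation (input). The cells were HEK293T, a human embryonic kidney line. The 8 samples were 4 immunoprecipitates (IP) and their 4 inputs. Of each, 2 came from cells treated with a control siRNA and 2 from PCIF1 knockdown cells. PCIF1 is the methyltransferase that adds the N6-methyl group to a 2'-O-methylated adenosine next to the mRNA cap, which gives m6Am. Antibodies against m6A also bind m6Am. The comparison therefore asks which IP peaks differ with PCIF1 knockdown, and in particular whether those at transcript 5' ends do. RNA levels were not measured here, so a change in a peak call is not told apart from a change in RNA abundance. After removal of reads at repeated positions, 8979882 tags remained in control 1, 8558479 in control 2, 8413725 in knockdown 1 and 9483952 in knockdown 2. Their inputs kept 11911707, 11887640, 12235106 and 11978673 tags. Labels give a replicate number but do not say whether replicates were separate cultures, so p-values over libraries measure the spread between these libraries, which may be technical. Intervals cover counting error only. All positions are in hg19.

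PCIF1 itself held 1 region, at its stop codon (chromosome 20, 44576277 to 44576589, plus strand), and all 4 lists contained it. The authors' fold over input there was 2.85 in control 1, 2.86 in control 2, 6.26 in knockdown 1 and 7.08 in knockdown 2. Those values stood at the 25.9th and 23.5th percentile of folds within the control lists and at the 86.6th and 90.4th within the knockdown lists. A peak list gives no RNA level, so the extent of the knockdown was not measured here.

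Most peaks lay near stop codons, in coding sequence and in 3' UTRs in every library, and the 5 regions in all 4 lists that ranked highest by fold in the control lists lay outside the 5' end. Folds are given for control 1, control 2, knockdown 1 and knockdown 2 in turn. TOR1AIP2 had an intronic region on chromosome 1 (179821837 to 179822122) with 18.3, 12.7, 9.36 and 12.0. The zinc finger gene ZNF606 had a coding region on chromosome 19 (58489123 to 58491618) with 12.3, 13.4, 6.15 and 9.56. The RNA-editing deaminase gene ADARB1 had a region in a non-coding exon on chromosome 21 (46565370 to 46566131) with 12.0, 11.8, 5.75 and 12.8. The pseudogene CSPG4P8, on chromosome 15 (82753317 to 82754320), had folds of 25.5, 15.2, 23.5 and 6.19. Pseudogene copies can share reads, so its values are uncertain. Stop codon peaks made up 23.1% ± 0.0824 (SD, n = 2) of control peaks and 23.4% ± 1.15 (SD, n = 2) of knockdown peaks (exact permutation test, two-sided, p = 1). Coding peaks made up 24.2% ± 0.159 and 23.1% ± 0.649, and 3' UTR peaks 16.5% ± 0.0885 and 15.8% ± 0.296 (SD, n = 2 each, exact permutation p = 0.333 for both). Peaks in non-coding exons took 11.5% ± 0.216 in controls and 12.6% ± 0.479 in knockdowns, and intergenic peaks 3.90% ± 0.128 and 4.78% ± 0.343 (SD, n = 2 each, exact permutation p = 0.333 for both). Intronic peaks took 14.3% ± 0.0633 and 14.0% ± 1.05 (SD, n = 2 each, exact permutation p = 1), and 5' UTR peaks away from an annotated start 2.92% ± 0.0543 and 2.75% ± 0.00509 (SD, n = 2 each, exact permutation p = 0.333). With 2 libraries against 2, the smallest two-sided p that the exact permutation test allows is 0.333, so none of these comparisons could reach 0.05. Without knockdown 1, the stop codon share was lower in the remaining knockdown library than in the controls, by a difference of -0.56 percentage points, and the intron share higher by 0.472 points.

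**Figure D1:**
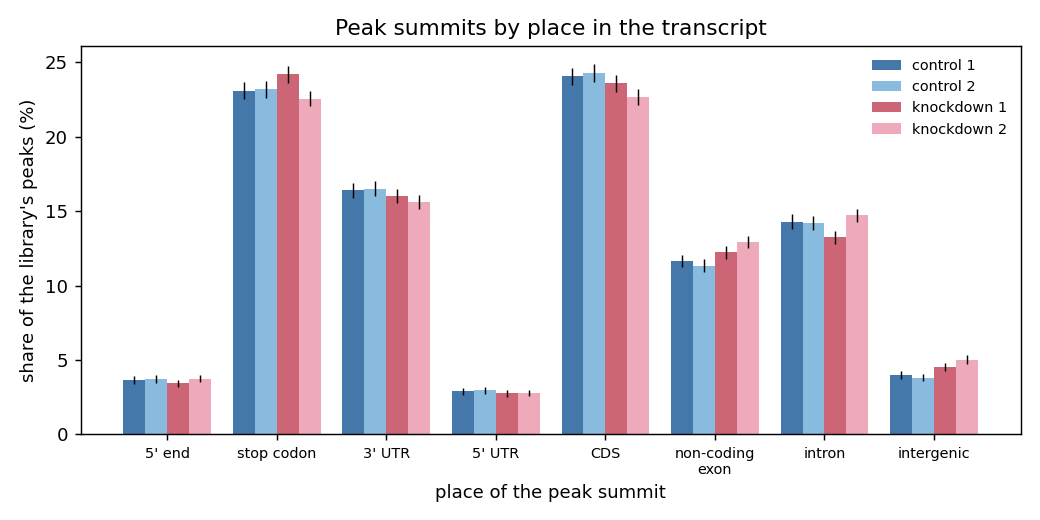
Share of each library's peaks (y axis, percent) whose summit lay in each part of the annotation (x axis), with 1 bar per IP library and 95% Wilson intervals as error bars. Stop codon and coding peaks lead in every library, and 5' end peaks take between 3.42% and 3.73%.

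The question of PCIF1 dependence was put first to the 5' end class, the peaks whose summit lay from 100 nt upstream to 200 nt downstream of an annotated start of a protein-coding transcript. This class took 3.66% of peaks in control 1 (767 of 20937, 95% Wilson interval 3.42 to 3.93), 3.70% in control 2 (779 of 21069; 3.45 to 3.96), 3.42% in knockdown 1 (739 of 21613; 3.19 to 3.67) and 3.73% in knockdown 2 (904 of 24242; 3.50 to 3.98). The group means were 3.68% ± 0.0240 and 3.57% ± 0.219 (SD, n = 2 each, exact permutation test, two-sided, p = 1), so their difference was smaller than the spread between the knockdown libraries. The 5' end regions named next were in all 4 lists and ranked highest among such regions by fold in the control lists. Folds are in the same order of libraries. That of the transcription factor gene NFIB on chromosome 9 (14313508 to 14313948) had folds of 11.7, 10.3, 12.1 and 6.28. That of the collagen gene COL13A1 on chromosome 10 (71561685 to 71562094) had 10.1, 11.4, 10.3 and 7.49. NAMPT, an enzyme of NAD synthesis, had 8.28, 12.0, 9.26 and 10.8 on chromosome 7 (105926004 to 105926561). The homeobox genes NKX2-3 on chromosome 10 (101292681 to 101293145) and MEIS1 on chromosome 2 (66662256 to 66662617) had 8.97, 8.48, 6.19 and 5.16, and 9.96, 8.39, 6.71 and 6.27.

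Regions held in both controls and in neither knockdown are called control-only here, and the reverse knockdown-only. Of 625 5' end regions in both controls, 44 were control-only, 7.04%, against 1141 of 16349 other regions, 6.98% (odds ratio 1.01, 95% interval 0.739 to 1.38, Fisher's exact test over regions, two-sided, p = 0.936). Of 625 in both knockdowns, 70 were knockdown-only, 11.2%, against 2058 of 17711, 11.6% (odds ratio 0.959, interval 0.745 to 1.24, Fisher's exact p = 0.799). The 10 strongest control-only 5' end regions follow with their folds in control 1 and control 2. The ephrin receptor gene EPHA4 had 6.38 and 7.47 on chromosome 2 (222438597 to 222439004). The potassium channel gene KCNJ2 had 6.38 and 9.66 on chromosome 17 (68164573 to 68165097). The apoptosis regulator gene CFLAR had 5.70 and 6.80 on chromosome 2 (201980863 to 201981104). FSIP1 had 5.18 and 9.18 on chromosome 15 (39892910 to 39893287). CAVIN4 had 5.97 and 4.88 on chromosome 9 (103340350 to 103340698). The transcription factor gene ETS2 had 5.73 and 4.78 on chromosome 21 (40177677 to 40177901). NUDT11 had 4.56 and 5.51 on chromosome X (51239437 to 51239672). C4orf3 had 4.74 and 4.54 on chromosome 4 (120221609 to 120221820). The ubiquitin ligase gene CBLB had 4.68 and 4.51 on chromosome 3 (105572334 to 105572584). MBD5 had 5.66 and 4.41 on chromosome 2 (148778710 to 148779066). At a -log10 q of 10 or more, EPHA4, KCNJ2, CFLAR, FSIP1 and ETS2 were no longer control-only. The 5 strongest knockdown-only ones follow with their folds in knockdown 1 and knockdown 2. The linker histone gene H1-3 had 9.95 and 8.50 on chromosome 6 (26235073 to 26235479). NUDT6 had 7.85 and 10.6 on chromosome 4 (123843586 to 123844435). TMEM144 had 6.82 and 12.8 on chromosome 4 (159122270 to 159123033). RAG2, a V(D)J recombinase gene, had 6.31 and 6.58 on chromosome 11 (36616093 to 36616320). The phosphodiesterase gene PDE4D had 6.04 and 8.72 on chromosome 5 (59064267 to 59064833). At the same stricter threshold RAG2 and PDE4D were no longer knockdown-only. The gene named for a 5' end region is that of the nearest annotated start on either strand. Summits lay upstream of that start in H1-3 (-96 nt), TMEM144 (-84 nt), NUDT6 (-23 nt), PDE4D (-21 nt), NUDT11 (-72 nt) and KCNJ2 (-59 nt). These regions may therefore belong to other transcripts.

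These tests over regions describe these 4 lists, since regions are not replicates. The result for 5' end regions changed with how loss was defined. Of the 625, 133 were absent from at least 1 knockdown list, 21.3% against 15.2% of other regions (odds ratio 1.51, interval 1.24 to 1.84, Fisher's exact p = 7.3e-05). The crossed pairings of libraries gave 1.28, 1.42, 1.35 and 1.39 for the same measure (Fisher's exact p = 0.0653, 0.00125, 0.00692 and 0.00917), so odds ratios above 1 were found without the group contrast too, and 3 of these 4 passed 0.05. In the opposite direction, 133 of the 625 in both knockdowns were absent from at least 1 control list, 21.3% against 21.7% (odds ratio 0.976, interval 0.803 to 1.19, Fisher's exact p = 0.843). At the stricter threshold of a -log10 q of 10 the odds ratio of being control-only was 1.51 (Fisher's exact p = 0.0265), and when the peak itself had to cover the annotated start it was 0.600 (p = 5.9e-04). With peaks covering the start the odds ratio of being knockdown-only was also lower, 0.701 (Fisher's exact p = 9.9e-04). Without knockdown 2 the odds ratio of being control-only was 1.35 (Fisher's exact p = 0.00953), and without knockdown 1 the odds ratio of being knockdown-only was 1.17 (p = 0.0482). With only other regions in exons of protein-coding transcripts as the comparison, chosen after the data were seen, 5' end regions were more often control-only, 7.04% against 3.45% (odds ratio 2.12, interval 1.54 to 2.93, Fisher's exact p = 2.3e-05). They were also more often knockdown-only, 11.2% against 6.70% (odds ratio 1.76, interval 1.36 to 2.27, Fisher's exact p = 5.0e-05).

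The first transcribed base was examined because m6Am needs an adenosine there. Among the named control-only regions, the annotated start nearest to the summit began with A in EPHA4 (ACGCGTGCTCA), FSIP1 (ATGAGCAGGAG), NUDT11 (AGACGGAGGCG) and MBD5 (AAGCAGAGAGA), with G in CFLAR, CAVIN4, ETS2 and C4orf3, with T in KCNJ2 and with C in CBLB. Of 222 5' end regions in both controls whose start was A, 15 were control-only, 6.76%, and of 403 with another base, 29, 7.20% (odds ratio 0.935, interval 0.490 to 1.78, Fisher's exact test, two-sided, p = 0.872). A start at A was found in 34.1% of the 44 control-only regions (95% Wilson interval 21.9 to 48.9), 38.6% of the 70 knockdown-only regions (28.0 to 50.3) and 37.0% of the 492 5' end regions in all 4 lists (32.8 to 41.3). Annotated starts are imprecise. At the lower quartile of the 492 regions the summit lay at -24 nt from the start, and it lay at -59 nt in KCNJ2 and -72 nt in NUDT11. The start in use may therefore differ from the annotated one, so this comparison cannot decide whether loss depends on the first base.

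Internal m6A lies in the consensus DRACH (D = A, G or T; R = A or G; H = A, C or T). NFIB, NAMPT, NKX2-3, CFLAR, FSIP1, NUDT11, NUDT6 and PDE4D each had a GGACT, the core form of that motif, as the DRACH nearest to the summit, within 22 nt of it. EPHA4, KCNJ2, CAVIN4, ETS2, C4orf3, CBLB, MBD5, H1-3, TMEM144, RAG2, COL13A1 and MEIS1 had another form nearest. That form lay at 65 nt from the summit in MBD5 and at -77 nt in RAG2. Outside the 5' end, 97.7% of control-only regions and 99.0% of those not lost had a DRACH within 100 nt of the summit (odds ratio 0.429, interval 0.277 to 0.663, Fisher's exact test, two-sided, p = 4.9e-04), against 96.3% and 96.1% of windows 1000 nt away. At the stricter threshold that odds ratio was 0.631 (Fisher's exact p = 0.288). At the 5' end the shares were 95.5% of control-only and 96.2% of other regions (odds ratio 0.826, interval 0.188 to 3.63, Fisher's exact p = 0.683). The motif was in 95.5% and 94.6% of background windows, so a window of this width nearly always held the motif. The narrower GGACT was found in 26.9% of control-only and 32.2% of kept regions outside the 5' end, against 16.1% and 15.4% of background windows, and in 25.0% of 44 control-only and 35.8% of 581 kept 5' end regions, against 20.5% and 16.8%.

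Across all transcript parts, the 2 groups differed more than libraries within them. Most group-specific regions lay outside the 5' end, as most regions did. The 5' end held 114 of the 3313 group-specific regions and 1168 of all 29727 regions. The strongest control-only regions outside the 5' end follow with folds in control 1 and control 2. PARD3B had an intronic one with 12.0 and 9.79 (chromosome 2, 205422954 to 205424669). The prostaglandin receptor gene PTGFR had an intronic one with 9.61 and 9.43 (chromosome 1, 78870266 to 78871249), and CHMP4C one with 11.4 and 9.12 (chromosome 8, 82645824 to 82646239). In 3' UTRs, DMRT3 had 9.17 and 11.0 (chromosome 9, 990827 to 991720) and CNTNAP3B had 9.08 and 10.6 (chromosome 9, 43920698 to 43921006). The strongest knockdown-only regions follow with folds in knockdown 1 and knockdown 2. Exons of the non-coding RNAs LINC01894 and LINC02014 had 11.4 and 12.4 (chromosome 18, 22512960 to 22513697) and 10.0 and 12.4 (chromosome 3, 129809654 to 129810092). The coding sequence of the kinase gene FRK had 10.4 and 12.8 (chromosome 6, 116381207 to 116381806). An intron of CADM4 had 9.68 and 10.1 (chromosome 19, 44135711 to 44136140). The 3' UTR of PDGFB had 10.7 and 9.96 (chromosome 22, 39620734 to 39621218). The 4 lists merged into 29727 regions, of which 14360, 48.3%, were in all 4 lists, 1185 were control-only and 2128 knockdown-only. With lists of equal length the counts were 1494 and 1640. Pairing the libraries across groups gave 801 and 806 regions specific to a pair of libraries, so the 3313 group-specific regions were 4.11 times the larger of these counts. At a fold of 4 or more this ratio was 2.62. The control lists held 20945 and 21079 peaks and the knockdown lists 21623 and 24247, with means of 21012 ± 94.8 and 22935 ± 1855 (SD, n = 2 each, exact permutation test, two-sided, p = 0.333). A peak of 1 list was overlapped in another, over at least 50% of the shorter peak, for 77.8% to 88.1% of peaks within a group and 71.3% to 83.2% between groups, with means of 83.3% and 77.7%. Leaving out knockdown 1 or knockdown 2 moved the number of knockdown-only regions to 5249 or 3531, and leaving out control 1 or control 2 moved that of control-only regions to 2724 or 2619, because a group is then held by 1 list.

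Knockdown-only regions outnumbered control-only ones in 7 of the 8 classes, with longer lists in the knockdown. With lists of equal length the 5' end had 59 control-only and 54 knockdown-only regions. In 5' UTRs away from a start the counts were 37 control-only and 30 knockdown-only. At stop codons 76 of 4348 regions in both controls were control-only, 1.75% (95% Wilson interval 1.40 to 2.18), and 343 of 4790 in both knockdowns were knockdown-only, 7.16% (6.46 to 7.93). In introns the counts were 456 of 1972, 23.1% (21.3 to 25.0), and 543 of 2077, 26.1% (24.3 to 28.1), and in 3' UTRs 182 of 2883, 6.31% (5.48 to 7.26), and 228 of 2998, 7.61% (6.71 to 8.61). Set against all other group-specific regions, stop codon regions were more often knockdown-only (odds ratio of control-only to knockdown-only 0.357, Fisher's exact p = 5.0e-17, Benjamini-Hochberg adjusted over the 8 classes 4.0e-16), as did non-coding exons (0.691, p = 1.7e-04, adjusted 3.4e-04) and intergenic regions (0.713, p = 0.00642, adjusted 0.00856). Introns (1.83, Fisher's exact p = 1.2e-14, adjusted 4.6e-14), 3' UTRs (1.51, p = 1.4e-04, adjusted 3.4e-04) and 5' UTRs away from a start (2.25, p = 0.00115, adjusted 0.00185) were less often knockdown-only than the other classes. The stop codon odds ratio was 0.737 without knockdown 1, 0.565 without knockdown 2 and 0.587 at a fold of 4. Neither the coding sequence (0.827, Fisher's exact p = 0.108, adjusted 0.124) nor the 5' end (1.13, p = 0.551, adjusted 0.551) passed. This comparison by class was chosen after the data were seen. The call ended for 5' UTRs at the stricter threshold (1.31, Fisher's exact p = 0.348) and at a fold of 4 (1.63, p = 0.125). It ended for 3' UTRs at a fold of 4 (1.1, Fisher's exact p = 0.505) and for intergenic regions at the stricter threshold (0.804, p = 0.281). Without control 2 all 3 calls ended (1.15, 1.04 and 0.953, in that order of classes). The 3' UTR call also ended without control 1 (1.15, Fisher's exact p = 0.0908). Relative to other classes, coding regions were more often knockdown-only without control 1 (0.831, Fisher's exact p = 0.0267) or control 2 (0.725, p = 1.0e-04). 5' end regions were less often knockdown-only at the stricter threshold (1.66, Fisher's exact p = 0.0377) and without control 2 (1.36, p = 0.0271) or knockdown 2 (1.35, p = 0.0289).

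**Figure D2:**
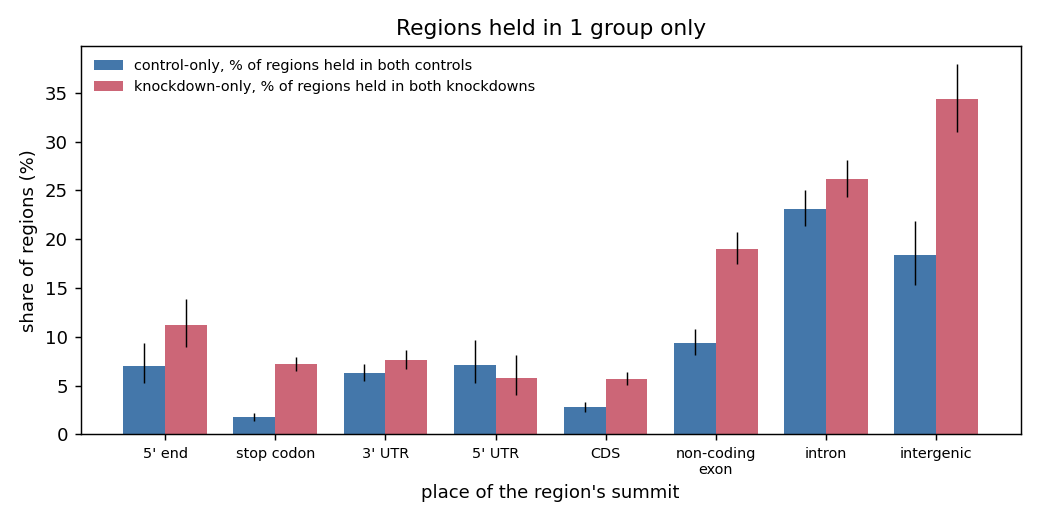
Share of regions (y axis, percent) that were control-only among those held in both controls, or knockdown-only among those held in both knockdowns, by place of the summit (x axis), with 95% Wilson intervals as error bars. Stop codon regions were control-only in 1.75% and knockdown-only in 7.16%, and introns had 23.1% and 26.1%.

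Knockdown-only regions were richer in G and C than control-only regions, most of all in introns and 3' UTRs. Over 100 nt on either side of the summit, the median GC content was 43.8% in the 1185 control-only regions, 51.7% in the 2128 knockdown-only regions and 49.3% in the 14360 regions in all 4 lists. The difference was 7.96 percentage points (95% bootstrap interval over regions 6.97 to 8.96, permutation test over regions, two-sided, p = 1e-05, the smallest that the permutations can give). In introns the difference of medians was 11.9 points (interval 9.95 to 13.4), in 3' UTRs 9.45 points (7.21 to 11.7) and in intergenic regions 7.46 points (4.48 to 9.45). At stop codons it was 3.23 points (-0.746 to 6.47), and at the 5' end -0.249 points (-6.97 to 4.98). Without knockdown 2 the difference over all classes was 3.98 points, and without knockdown 1 it was 9.45 points. GC content was compared after the lists had been seen.

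**Figure D3:**
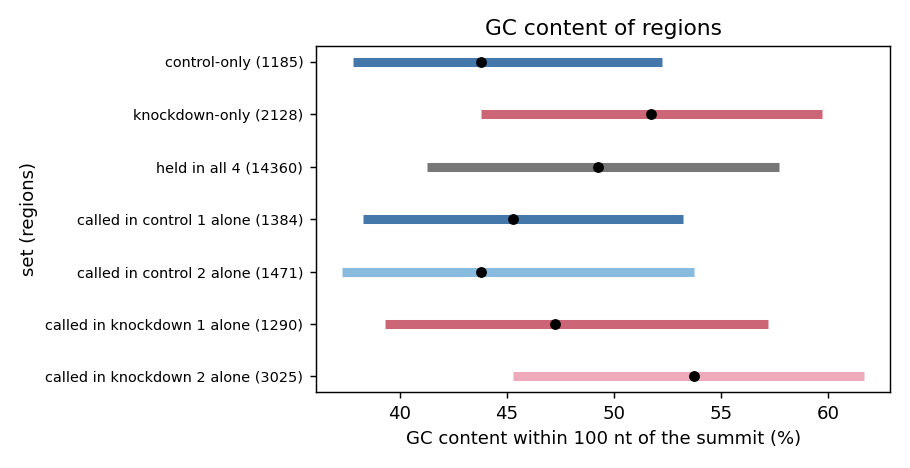
GC content within 100 nt of the summit (percent) for control-only regions, knockdown-only regions, regions in all 4 lists and regions called in 1 library alone, with points for medians and lines from the lower to the upper quartile. The medians were 43.8% for control-only, 51.7% for knockdown-only and 53.7% for regions called in knockdown 2 alone.

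The genes that write, read and remove m6A and cap methylation had 72.1% of their regions in all 4 lists, against 68.5% of all 20950 regions held in both libraries of a group (Fisher's exact test against other regions, two-sided, chosen after the data were seen, p = 0.602). Of the 34 genes of this list, 31 had a region in both libraries of a group and 27 had at least 1 region in all 4 lists. Among these were the m6A writer components METTL14, WTAP, VIRMA, ZC3H13 and RBM15, the demethylase gene FTO, the cap 2'-O-methyltransferase gene CMTR2 and the readers YTHDF1, YTHDF2, YTHDF3, YTHDC1 and YTHDC2. Of their 68 regions, 49 were in all 4 lists, 1 was control-only, 3 were knockdown-only and 15 were in other combinations. The control-only region was at the stop codon of the cap guanine-N7 methyltransferase gene RNMT (chromosome 18, 13762006 to 13762232, folds 1.81 and 2.75 in the controls). The knockdown-only ones were at the stop codons of ZCCHC4 (chromosome 4, 25370618 to 25370861; 4.24 and 2.49 in the knockdowns) and of the demethylase gene ALKBH5 (chromosome 17, 18111434 to 18111797; 1.70 and 1.90), and in an intron of HNRNPA2B1 (chromosome 7, 26215623 to 26215921; 5.12 and 3.40). CBLL1, a subunit of the m6A writer complex, had the 1 5' end region of the list, on chromosome 7 (107383305 to 107383904), and it was in all 4 lists with folds of 7.81, 5.62, 7.22 and 6.42.

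Of the 13 gene lists fixed before the data were examined, none differed from other genes in control-only regions after adjustment over the lists, at the 5' end or elsewhere. At an unadjusted p below 0.05 there was 1. That list was the cytosolic ribosomal proteins, in which both genes with a 5' end region in both controls, RPL8 (chromosome 8, 146017335 to 146017587, folds 1.5 and 1.51) and FAU (chromosome 11, 64889094 to 64889414; 2.21 and 2.31), had lost it, against 6.98% of other genes (Fisher's exact test, two-sided, p = 0.00519, Benjamini-Hochberg adjusted p = 0.0571). In the same list the 1 gene with a 5' end region in both knockdowns, RPL30, named after its values were seen, had gained it (Fisher's exact test, p = 0.113, adjusted 0.622). RPL8 ranked at the 0.261th percentile of folds in its lower list, so the peak was among the weakest there. Mitochondrial ribosomal proteins lost 0 of 3, with MRPL51, MRPS21 and MRPL28 in all 4 lists. Translation factors lost 0 of 3, with EEF1D, EIF2S1 and PABPC1 in all 4 lists. Cell cycle genes lost 0 of 3, with CDKN1B, E2F3 and PCNA in all 4 lists. Chaperones lost 0 of 2, with HSPA1B in all 4 lists and BAG3 missing from knockdown 2. Splicing factors lost 0 of 2, with PRPF31 in all 4 lists and HNRNPU missing from knockdown 2. Oxidative phosphorylation lost 0 of 1 (ATP5MC2) and methylation machinery 0 of 1. Chromatin regulators lost 1 of 10, BRD2, a bromodomain protein gene outside the naming rule and named after its values were seen. ARID1B, SETD1A and CHD8 were in all 4 lists and KDM2B was missing from knockdown 1. Zinc finger genes lost 1 of 19, ZNF747, likewise outside the rule, with ZNF577, ZNF608 and ZNF18 in all 4 lists and ZNF827 missing from knockdown 1. Replication-dependent histones lost 1 of 2, H2BC12 on chromosome 6 (27114410 to 27114618, folds 2.49 and 3.07), and HIST2H2AA3 was in all 4 lists (adjusted p between 0.773 and 1 for these lists). Of 4 histone genes with a 5' end region in both knockdowns, 2 had gained it, H1-3 and H2BC21, the latter named after its values were seen (Fisher's exact test, p = 0.0651, adjusted 0.622). Interferon-stimulated genes and markers of other cell types (blood, liver, muscle and neurons) had no 5' end region in both controls. Elsewhere 6 and 2 of their genes had one, of which 1 and 0 were control-only (Fisher's exact test, adjusted p = 0.944 and 1).

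Knockdown-only regions outside the 5' end, a direction of the list test that was planned for losses alone, were less frequent in 2 lists. Among zinc finger genes, a large family of mostly KRAB-type transcription factors, 31 of 396 had one, 7.83%, against 15.3% of other genes (odds ratio 0.471, Fisher's exact test, two-sided, p = 1.5e-05, adjusted 1.9e-04), and 28 of 391 had a control-only one, 7.16% against 9.59% (p = 0.113, adjusted 0.944). At the stricter threshold the first odds ratio was 0.709 (Fisher's exact p = 0.0589). Among mitochondrial ribosomal proteins 0 of 35 genes gained a region, against 15.0% of other genes (Fisher's exact p = 0.00696, adjusted 0.0453). Of 42, 3 had a control-only one, MRPL2, MRPL23 and MRPL37, named after their values were seen (Fisher's exact test, adjusted p = 0.944). The other genes in these tests include non-coding genes and were not matched for place or number of regions. By region, 44 of 697 in zinc finger genes and 0 of 40 in mitochondrial ribosomal protein genes were knockdown-only. The share was 11.6% of all 17711 regions outside the 5' end and 6.70% of the 12739 in mRNA exons. The zinc finger share lay near the mRNA exon share and below the share of all regions. The make-up of the background was therefore not ruled out as a source.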

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

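Comparisons with mRNA exon regions, and all alternatives for knockdown-only regions, GC content, the direction by class, absence from at least 1 list and gained zinc finger regions, were chosen after the data were seen. Apart from named regions, 184 of 250 alternatives kept direction and side of the threshold or stayed within the spread, 14 were weaker, 11 stronger, 11 moved and 30 reversed. Of 903 alternatives for 129 named regions, 777 stayed, 124 moved and 2 reversed. Odds ratios for 5' end regions lie near 1, so a reversal is often a small step. Except where a setting holds fewer peaks or 1 list per group by construction, the cause was not tested. With 2 libraries per group, p-values over libraries say nothing about stability.

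At a -log10 q of 10, which keeps fewer peaks, control-only regions numbered 712 and knockdown-only 1318. Odds ratios were 1.51 for 5' end regions being control-only, 1.02 for a first base A, 0.631 for DRACH outside the 5' end and 0.709 for gained zinc finger regions, and for control-only against knockdown-only 1.66 at the 5' end, 1.31 in 5' UTRs and 0.804 between genes. The share of a group's lists holding a region of IGF2BP3 on chromosome 7 (start 23509639), knockdown minus control, went from -0.5 to 0.5. At a fold of 4 the odds ratio of loss was 0.982, the ratio to the crossed count 2.62, the GC difference 6.47 points, and control-only against knockdown-only 1.1 in 3' UTRs, 1.63 in 5' UTRs and 1.06 in coding sequence. With lists of equal length the 5' end DRACH odds ratio was 1.15 and that difference for a region of IGF2BP2 on chromosome 3 (start 185362136) went from 0.5 to -0.5. Peak by peak, the odds ratio of 5' end gain was 1.04 at 50% of the shorter peak and 1.01 at reciprocal overlap.

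With the window from 50 nt upstream to 100 nt downstream, the difference in 5' end share was 0.0411 points and the odds ratios were 0.786 for loss, 1.24 for gain, 1.41 for first base A and 1.18 for absence from a knockdown rather than a control list. From 200 nt upstream to 500 nt downstream the share differed by 0.139 points and gain had 1.1. With peaks covering the start, the share differed by 0.0127 points, loss had 0.600, gain 0.701 and absence 1.08. With the most upstream start, gain had 1.40, first base A 1.1 and absence 1.44. The call for absence ended in the narrower window, with peaks covering the start and with the most upstream start. Loss from at least 1 list had 1.51, against 1.28 to 1.42 in the crossed pairings. Against other mRNA exon regions loss had 2.12 and gain 1.76.

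With replicate number as a block, the odds ratios were 1.35 for loss (p = 9.1e-07), 1.08 for gain and 1.01 for first base A. That block counts absence from single lists, and the numbers did not pair the libraries (correlation over regions of control 1 minus 2 with knockdown 1 minus 2, -0.0037).

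Leaving out 1 replicate at a time leaves 1 list in a group. Control-only regions then ranged from 1680 to 2724 and knockdown-only regions from 3033 to 5249, the GC difference from 3.98 to 9.45 points, and the difference in share from -0.261 to 0.0487 points at the 5' end, -0.564 to 1.07 at stop codons and -1.01 to 0.472 in introns. Odds ratios ranged from 1.17 to 1.35 for loss, 0.966 to 1.17 for gain, 0.623 to 1.11 for first base A, 0.857 to 2.67 for 5' end DRACH and 1.1 to 1.48 for absence. Control-only against knockdown-only ranged from 1.06 to 1.36 at the 5' end, 0.342 to 0.737 at stop codons, 1.04 to 1.63 in 3' UTRs, 1.15 to 1.85 in 5' UTRs, 0.725 to 1.09 in coding sequence and 0.653 to 0.953 between genes. Depth limits these lists to peaks that passed the threshold, so absence from a list is not absence of methylation.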

Other observations

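The tests on depth, tag length, place in the transcript, library bias in GC content, a single knockdown library and the C-then-A start were chosen after the results they measure were seen. The genes with the most group-specific regions, named here after their values were seen, mostly held them in 1 part of the gene, RNF213 and ZNF195 being exceptions. PTGFR, a prostaglandin receptor gene, had 7 control-only regions, all intronic, between 78846416 and 78926512 on chromosome 1, with a median GC content of 34.3% and 1 region in all 4 lists. ZNF277-AS1 had 4 control-only regions, and CCDC138, CD58 and CENPQ had 3 each, also all intronic. On the knockdown side AHNAK2 had 9 knockdown-only regions, all in coding sequence, between 105406586 and 105420955 on chromosome 14, with a median GC content of 60.2%. ZNF195 had 6, of which 5 were intronic and 1 at the stop codon. MCF2L had 5 intronic ones and KIAA0513 had 4 in its 3' UTR. RNF213 had 5, of which 3 were in non-coding exons, 1 in coding sequence and 1 in an intron. None of these 10 genes had a region in the opposite direction.

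In 439 5' end regions with 1 peak in each list, the median shift along the gene, knockdown minus control, was 1.5 nt (95% interval 0.5 to 2.5), as it was in 387 regions of 5' UTRs (0.5 to 3.5), and in 3775 stop codon regions it was 0 nt. In the 439 regions the shift was 1 nt for knockdown 2 minus knockdown 1 and 0 nt for control 2 minus control 1. Their median absolute shift was 15.5 nt. These regions were held in all 4 lists, and only 37.0% of such 5' end regions had an annotated start at A, so the shift of 1.5 nt leaves a loss of cap-adjacent m6Am open. Among group-specific 5' end regions, those whose annotated start read C then A were control-only in 8 and knockdown-only in 17, against 36 and 53 of the others (odds ratio 0.693, interval 0.270 to 1.78; Fisher's exact p = 0.494), which leaves that question open.

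Group-specific regions outnumbered those of the crossed pairings by 4.11 (interval 3.81 to 4.44), or 2.62 at a fold of 4, and the crossed pairing of the deeper and the shallower libraries is among these, which argues against depth. Within bins of GC content the smallest ratio was 3.81 (3.16 to 4.58). A GC bias shared by the libraries of a group would act within each bin too, so this test cannot decide on GC content. Tag length differed by 17 bp between the knockdown libraries and by 16 bp between control 2 and knockdown 1, yet the Jaccard index of knockdown 1 with knockdown 2 exceeded that with control 2 by 0.0615 (0.0549 to 0.0675), which argues against tag length as the whole source. Knockdown 1 was still closer to the controls than knockdown 2 was, by 0.0204. An effect of PCIF1 knockdown may contribute, as a hypothesis. Changes in RNA abundance, which was not measured, and other differences between preparations of the groups stay open.

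The higher GC content of knockdown-only regions was present in 7 of 8 classes by over 1 point. In 3 of the 7 the interval included 0: stop codons, 5' UTRs (7.21 points, -0.995 to 14.4) and coding sequence (4.48, -0.498 to 8.96). In introns, 3' UTRs, non-coding exons (5.97, 3.48 to 7.96) and intergenic regions it lay above 0, which argues against place in the transcript as the whole source. With lists of equal length the difference stayed at 7.96 points (lower bound 6.97), which argues against list length. Regions called in knockdown 2 alone exceeded those called in knockdown 1 alone by 6.47 points (5.47 to 7.96), so a GC bias of single libraries could account for much of the difference and stays open. No biological explanation was tested for it.

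5' end regions were absent from at least 1 knockdown list rather than at least 1 control list more often than other regions were (odds ratio 1.55, interval 1.21 to 1.98; Fisher's exact p = 5.3e-04), while the crossed pairings gave 0.901 (0.666 to 1.22) and 0.972 (0.724 to 1.30). Lists of equal length gave 1.49 (1.16 to 1.91) and bins of GC content 2.00 (1.56 to 2.57), which argue against list length and GC content. Without knockdown 1 the odds ratio was 1.1 (0.849 to 1.42), and the call ended. Without knockdown 2 it was 1.29 (1.02 to 1.65). A single knockdown library may therefore account for the difference. The call also ended with a window of 50 nt upstream to 100 nt downstream (1.18, Fisher's exact p = 0.338), with peaks covering the start (1.08, p = 0.521) and with the most upstream start (1.44, p = 0.0679). Control-only 5' end regions had summits farther from the start (median 108 nt downstream) than those in both controls and not lost (59 nt) or knockdown-only ones (24.5 nt). In the narrower window 17 were control-only and 45 knockdown-only, against 1168 and 2083 of other regions (odds ratio 0.674, interval 0.384 to 1.18, Fisher's exact p = 0.183). With replicate number as a block, the odds ratio of loss for a first base A was 1.01, but annotated starts are too imprecise for this comparison to decide. These values neither show nor exclude a loss at the cap. A partial loss of cap-adjacent marks stays open only as a hypothesis.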
